A study of Mus musculus with 8 samples.

How the data were processed

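Hippocampal cells of 8 mice (4 exposed to lead through their dams, 4 controls, 2 females and 2 males in each group) were measured by single-cell RNA sequencing. Per the labels' protocols, mice were perfused with saline, the hippocampus was dissociated with enzymes in a heated tissue dissociator, and cells were frozen, thawed and loaded on a 10x Chromium. The deposited values are raw UMI counts per gene and cell in 1 table for all samples, as its whole numbers and differing totals show. Cell Ranger, Seurat and the mouse build mm10 are named in the submitters' processing notes; their roles, versions, the annotation and the filters are not given in the sources used here. In the deposited table each of the 5258 cells had at least 999 detected genes and 1137 UMIs, and each of the 17143 genes was present in at least 3 cells, so the authors' table had been filtered. A gene or cell removed at that step cannot be counted here, and the number of cells removed per mouse is not given in the sources used here. Cells were given to mice by the start of their column names, and 0 columns were left over. Whether counting used strand is not given either, so overlapping antisense genes are uncertain, as are near-identical gene families.

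Groups, comparisons, tests, filters, marker genes, 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Cells with under 200 genes or over 20% of UMIs from the 13 mitochondrial genes were removed (0 and 53 cells, the latter 33 from Pb and 20 from control mice; the highest share was 79.3%). Doublets were called per sample by Scrublet in scanpy (expected rate 0.02, seed 1): 33 cells, or 0.628%, of which 30 were still present after the mitochondrial filter and were removed (24 from Pb and 6 from control mice). Kept cells per mouse ranged from 211 to 1157 and their UMIs from 1749079 to 8508064. Summed UMIs per tested mouse ranged from 349827 to 1856482 in Microglia-like, 342333 to 2538170 in Oligodendrocyte-like, 176284 to 674445 in Pericyte-like, 148309 to 427724 in Smooth muscle-like and 48525 to 359709 in Astrocyte-like cells, and from 363605 to 1406564 in cluster 0, 149296 to 807232 in cluster 10 and 65558 to 176137 in cluster 11. Over all 28 pairs of samples, within and between the groups, chi-square per degree of freedom over genes was 4.54 to 56.3, so no pair agreed within sampling noise.

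Clustering used scanpy: counts scaled to 10000 per cell and log-transformed, 2000 variable genes chosen within samples (sex-linked and mitochondrial genes left out), values scaled with a maximum of 10, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 1.0, with no integration of samples. A cluster was named after the marker set with the highest mean log2 level over the other clusters (pseudocount 5 CPM) if at least 3 of its markers were detected in 10% of cells, the set led the next by 0.5 log2, and its top 10 genes (at least 0.2 UMIs per cell) held no more markers of another type than of its own. A median UMI count under 0.333 of the sample's also left a cluster unnamed where none of its markers led. Cluster 11 was left unnamed by hand, since its leading genes (Reln, Nhlh2, Lhx1) are not those of the immature neuron set that scored highest. These naming thresholds and that decision were set after the data were seen; the clusters they left unnamed are reported by number. Classes with at least 10 cells in enough mice were tested.

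UMI counts were summed per mouse and class. edgeR's quasi-likelihood test (TMM normalization, filterByExpr, sex as a covariate) gave Pb against control and male against female fold changes, and a model with the product of exposure and sex gave the interaction. Adjusted p-values are Benjamini-Hochberg values within a fit, with 0.05 as the threshold. CPM values are UMI counts of a gene scaled by the total of the class in a mouse. Class shares and library measures were compared by exact two-sided permutation tests over the 70 arrangements of 4 against 4 mice. Single-sample shares have 95% Wilson intervals. Gene lists with at least 5 tested members were tested with limma's camera on voom values (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over all lists and units together. The lists were those named in the report; list members can belong to more than 1 list (Hmox1, Cryab, Nfkbia and Cxcl10 among them), and Trf and Enpp2 of the further oligodendrocyte transcripts are also a metal list member and a choroid plexus marker. Gene positions come from GENCODE vM21 on GRCm38, matched by symbol.

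The named genes were, per unit, all genes past the threshold where there were 10 or fewer and otherwise the 5 with the largest rise and the 5 with the largest fall at a mean log2 CPM of at least 4 (10 and 10 in the class with most calls). Where none passed, they were the 3 with the smallest p, given as values. For the interaction and for sex, 3 up and 3 down were taken. Mt1, Mt2, Hmox1, Alad, Fech, Slc39a8, Slc11a2, Xist, Ddx3y, Uty, Eif2s3y and Kdm5d were always named, with 2 to 4 members of each called list with the smallest p. Other genes named as passing adjusted over a list alone, or as leading a cluster, were chosen after their values were seen.

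Each fit was tested on simulated data, with 200 genes changed by known folds among counts drawn from the real means and library sizes. For Pb against control in all cells (12720 genes), 4.17% of genes changed 1.5-fold were recovered, 46.0% at 2-fold, 86.0% at 4-fold and 98.0% at 8-fold, with 11 unchanged genes called. In Microglia-like cells (7968 genes) these shares were 22.9%, 60.0%, 100.0% and 100.0%, with 12 unchanged genes called, and in Oligodendrocyte-like cells (7774 genes) 18.0%, 77.1%, 100.0% and 100.0%, with 12. In Astrocyte-like cells (2362 genes) they were 8.33%, 38.3%, 98.0% and 100.0%, with 4. With no gene changed, 0 were called in all cells and 1 in Oligodendrocyte-like cells.

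Alternatives were DESeq2, limma-voom, DESeq2-style size factors, no filter on low counts, thinning to the lowest total, no sex covariate, the replicate number as a block, doublets kept, a mitochondrial limit of 10% or none, at least 500 genes per cell, at least 20 cells per mouse and class, Leiden resolutions of 0.5 and 2.0, mitochondrial and ribosomal protein genes left out, centred log ratios, arrangements within sex, and each mouse left out in turn. Chosen after seeing the data were Oligodendrocyte-like cells without cluster 19, all cells without Choroid plexus-like and Ependymal-like cells, other splits of the mice with no low-count filter, and an exact permutation test of list means. Principal components of the samples and divisions of the samples by their expression were looked at in exploration and used for no test. One gene that the rule names for the interaction is not reported here, so the interaction genes given are not the rule's full set. The classes too small for gene tests (Oligodendrocyte precursor-like cells among them) were left out of them. Versions were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, scikit-image 0.26.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.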

Results

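Single-cell RNA sequencing (10x Chromium, which tags each transcript molecule with a unique molecular identifier, UMI) was carried out on the hippocampus of 8 mice aged 5 months. In the exposed group, 4 mice (2 females and 2 males) were born to dams that drank water with 32 ppm lead (Pb) acetate from 2 weeks before mating until weaning, and had lead-free water afterwards. The control group held 4 mice (2 females and 2 males). Mice are named here by group, sex and number (Pb F1 is exposed female 1). Per the labels, 1 male and 1 female were kept from each litter; mice are not tied to litters there, so the p-values treat as independent mice that can share a dam.

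The deposited table held 17143 genes in 5258 cells, 214 to 1191 cells per mouse, against a target of 3000 to 5000 cells per sample in the labels. After filtering, 5175 cells were kept, 3555 from Pb mice and 1620 from control mice. Kept cells numbered 1157 in Pb F1, 471 in Pb F2, 1084 in Pb M1 and 843 in Pb M2, and 211 in control F1, 567 in control F2, 368 in control M1 and 474 in control M2. Total UMIs were 8508064, 3180582, 7669613 and 5252400 in the Pb mice and 1749079, 4306735, 2584016 and 3985848 in the control mice, in the same order. Pb mice gave 889 ± 309 cells and control mice 405 ± 153 (SD, n = 4 each; exact two-sided permutation test, p = 0.0857). Median UMIs per cell were 5884 ± 347 and 6295 ± 303 (SD, n = 4 each; exact permutation p = 0.171). Median genes per cell were 2365 ± 86.8 and 2444 ± 92.5 (SD, n = 4 each; exact permutation p = 0.257). The median mitochondrial share of UMIs was 3.24% ± 0.217 in Pb and 3.94% ± 0.475 in control mice (SD, n = 4 each; exact permutation p = 0.0571). Adjusted over these library measures, the exact permutation p-values lay between 0.171 and 0.257.

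The cells fell into 21 clusters, of which most carried markers of glia, blood vessels or immune cells. Microglia-like cells (1291), the resident macrophages of the brain, held 4 clusters: one was led by the inflammatory genes Il1a, Tnf and Nlrp3, one by Hmox1, Rgs1 and Tnfaip3, and one by P2ry13, Cx3cr1 and P2ry12. Oligodendrocyte-like cells (1276), which make myelin, held 3 clusters, and 69 of the 70 cells of cluster 19 came from control M2. They were most of the 92 Oligodendrocyte-like cells of that mouse. The other named classes were Pericyte-like (320), Astrocyte-like (272), Oligodendrocyte precursor-like (157), Smooth muscle-like (146), Choroid plexus-like (104), Perivascular macrophage-like (73, led by the antigen presentation genes H2-Aa and Cd74), Fibroblast-like (35), T or NK cell-like (27) and Ependymal-like (20). Clusters 0, 10, 11 and 15 were left unnamed. Cluster 0 (895 cells) and cluster 10 (424 cells) carried endothelial markers, but hemoglobin genes (Hba-a2, Hba-a1, Hbb-bt, Hbb-bs) led the former and Alpl, Cytl1, Sema3g and Bmx the latter. Cluster 11 (110 cells) was led by Snhg11, Reln, Nhlh2 and Lhx1, and cluster 15 (25 cells) included Gpr17, Rnd2 and Enpp6 among its leading genes.

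Whether lead exposure went with another cell composition was asked with the share of each class per mouse. Oligodendrocyte-like cells made up 26.1% ± 3.92 of the cells of Pb mice and 19.96% ± 0.915 of those of control mice (SD, n = 4 each), and each Pb mouse lay above each control mouse. Their share ran from 22.1% (95% Wilson interval 18.6 to 26.0) in Pb F2 to 30.2% (27.6 to 32.9) in Pb F1, and from 18.96% (14.2 to 24.8) in control F1 to 20.8% (17.7 to 24.3) in control F2. These intervals cover counting error only. The difference of 6.16 percentage points gave an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 mice allow, and an adjusted p = 0.429 over the 15 classes, so it failed the correction, which a single class cannot pass with 4 against 4 mice. Without a control mouse the exact permutation p rose to between 0.0571 (control M1 or F2, differences 6.39 and 6.45) and 0.0857 (control F1 or M2, differences 5.83 and 5.98). Oligodendrocyte precursor-like cells were 3.30% ± 0.943 in Pb and 1.91% ± 1.23 in control mice (SD, n = 4 each; exact permutation p = 0.143). Microglia-like cells were 24.6% ± 3.54 and 27.0% ± 2.60 (SD, n = 4 each; exact permutation p = 0.371), and Astrocyte-like cells 5.17% ± 2.63 and 4.46% ± 1.74 (SD, n = 4 each; exact permutation p = 0.629). The unnamed cluster 0 held 17.6% ± 4.47 of Pb and 18.5% ± 2.95 of control cells (SD, n = 4 each), and cluster 10 held 8.19% and 9.05%. Shares of the other 14 classes gave exact permutation p-values of 0.143 or more and adjusted values of 0.918 or more. How cells were dissociated, frozen and thawed can set such shares.

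**Figure D1:**
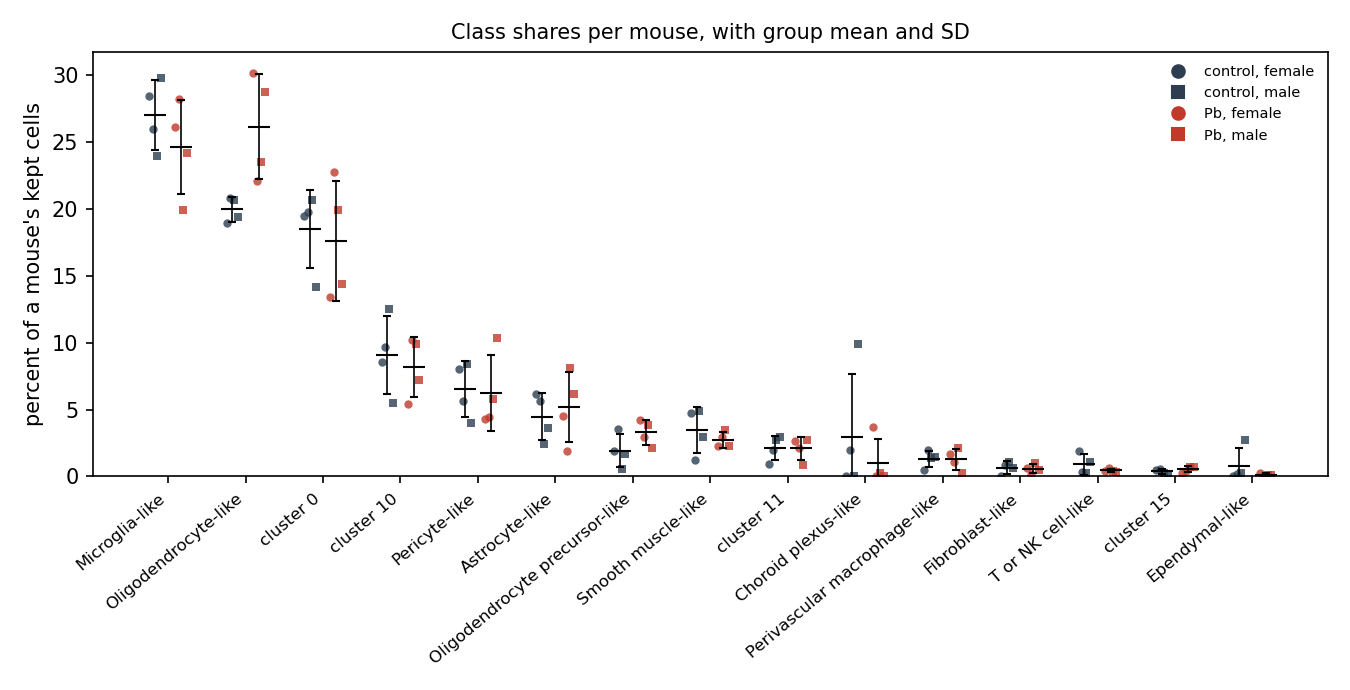
Percent of a mouse's kept cells in each class or unnamed cluster (vertical axis), with 1 point per mouse marked by exposure and sex, and the mean and SD of 4 mice per group. Oligodendrocyte-like cells average 26.1% in Pb and 19.96% in control mice, and for the other classes the groups overlap.

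Gene expression of Pb and control mice was compared in all cells and in 8 classes or clusters, by edgeR on UMIs summed per mouse with sex as covariate. In all cells, the genes with the smallest p were Ermn (myelin-associated cytoskeletal protein), Ptgds (prostaglandin D synthase) and Bcat1 (branched-chain amino acid transaminase). Each was higher in Pb mice, whose higher Oligodendrocyte-like share was not adjusted for. Ermn had a log2 fold change of 0.62 (SE 0.10; 456 ± 40.3 against 292 ± 29.6 CPM, SD, n = 4 each), Ptgds 0.73 (SE 0.13; 4920 against 2928 CPM) and Bcat1 1.28 (SE 0.23; 14.2 against 5.84 CPM). None passed across all genes in edgeR (adjusted p = 0.976) or limma-voom. DESeq2 called Ermn (adjusted p = 8.36e-08) and Ptgds (2.00e-06), which passed in no other setting run, and gave no adjusted p for Bcat1.

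By edgeR, 0 genes passed an adjusted p of 0.05 in any of the 9 units. The counts at an unadjusted p under 0.05 were 631 of 12640 genes in all cells, 331 of 7718 in Microglia-like, 320 of 7614 in Oligodendrocyte-like, 135 of 2285 in Astrocyte-like, 236 of 5505 in Pericyte-like and 207 of 4585 in Smooth muscle-like cells. They were 338 of 7300 in cluster 0, 259 of 5769 in cluster 10 and 33 of 1648 in cluster 11. DESeq2 called 29 genes in all cells (28 higher and 1 lower in Pb mice), 1 in Oligodendrocyte-like cells (Rbm3) and 0 elsewhere, and limma-voom called 0 in each unit. With no low-count filter edgeR called 60 genes in Microglia-like cells, 47 of which had passed the filter, 25 (19) in Oligodendrocyte-like cells and 0 in all cells. With no filter 11 of 34 splits of the mice, chosen as a test after seeing the data, gave as many in Microglia-like and 25 in Oligodendrocyte-like cells, and its smallest adjusted p was 2.12e-24 and 3.60e-49 there, so p-values of the fit with no filter are doubtful and no call here rests on them. Over all 42424 tests in the classes and clusters together, 0 passed in edgeR, with a smallest adjusted p of 0.780. Astrocyte-like cells and cluster 11 were tested with 3 mice per group and Smooth muscle-like cells with 4 Pb and 3 control mice. In edgeR, leaving out 1 mouse gave up to 11 calls in Astrocyte-like cells (Pb M1; 5 without Pb M2, 3 without Pb F1, 1 without control F1). It gave up to 6 in Smooth muscle-like cells (control M2; 1 without Pb M1) and 5 in Microglia-like cells (Pb F2; 1 without control M2). There were 3 calls in Oligodendrocyte-like cells (control M2), 1 in Pericyte-like cells (Pb F2), 1 in cluster 0 (control M2 or F2) and up to 2 in cluster 10 (control F2; 1 without Pb F1, Pb F2, control F1 or control M2).

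Within the classes, the genes with the smallest p are given as values, since none passed in edgeR with its low-count filter. In Microglia-like cells, the chemokine gene Cxcl10 had a log2 fold change of 1.22 (SE 0.25; 94.9 ± 24.1 against 41.2 ± 15.6 CPM, SD, n = 4 each; edgeR adjusted p = 0.533). The small heat shock protein gene Cryab had 0.66 (SE 0.14) and Gm43796, which has no position in the annotation used here, -0.94 (SE 0.21). In Oligodendrocyte-like cells, Rbm3, which encodes a cold-induced RNA-binding protein, stood at 109 ± 36.7 CPM in Pb and 210.4 ± 40.5 CPM in control mice (SD, n = 4 each; log2 fold change -0.96, SE 0.17, edgeR adjusted p = 0.358). DESeq2 gave -0.97 and an adjusted p = 0.00807. Rbm3 and Cxcl10 were also among the calls of the doubtful fit with no low-count filter (log2 fold changes -0.93 and 1.26). Hspa8 (0.48, SE 0.11) and Hspa1b (0.80, SE 0.19), both genes of the heat shock protein 70 family, followed. In Pericyte-like cells the first genes were Hsph1 (1.14, SE 0.23), the metallothionein gene Mt2 (-0.66, SE 0.14; 436 ± 133 against 693 ± 272 CPM, SD, n = 4 each) and Ankrd37 (1.14, SE 0.25), at an edgeR adjusted p = 0.488. Astrocyte-like cells gave Gm26825 (-1.80, SE 0.42), Hspa1a (0.99, SE 0.23) and Ppp1r14a (1.69, SE 0.45), and Smooth muscle-like cells Kif5a (-1.76, SE 0.35), Ptgds (1.05, SE 0.21) and Emp1 (1.38, SE 0.31). Cluster 0 gave Ermn (1.00, SE 0.24) and Baiap2l1 (-0.99) beside Ptgds (0.72), and cluster 10 gave Gm15013 (-1.81, SE 0.34), Abhd2 (-0.97, SE 0.19) and Igfbp3 (1.75, SE 0.37). Cluster 11 gave Cryab (1.17, SE 0.30), Hs3st1 (-1.22, SE 0.36) and Kif1b (1.08, SE 0.33). On GRCm38, Ermn lies on chromosome 2 from 58045113 to 58052864, Ptgds on chromosome 2 from 25466709 to 25470046 and Cxcl10 on chromosome 5 from 92346638 to 92348889. Cryab lies on chromosome 9 from 50751325 to 50756636 and Rbm3 on chromosome X from 8138975 to 8145880.

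Genes of metal handling and heme synthesis were named in advance because lead binds metallothioneins and inhibits enzymes of the heme pathway. Hmox1, which encodes heme oxygenase 1, had log2 fold changes from 0.09 to 0.75, above 0 in 5 of the 5 units where it was tested, but at -0.23 in cluster 0 and -0.02 in cluster 10 without Pb F1. It was 0.75 (SE 0.25) in Oligodendrocyte-like and 0.52 (SE 0.22; 560.0 ± 207 against 393 ± 56.4 CPM, SD, n = 4 each) in Microglia-like cells, where Pb F2 stood apart (7.98 log2 CPM; other Pb mice 9.30 to 9.45) and where it passed in edgeR only with no low-count filter (adjusted p = 0.0363), a fit whose p-values are doubtful, since 11 of 34 splits gave as many calls. Alad, the lead-sensitive enzyme delta-aminolevulinate dehydratase, ran from -0.35 to -0.05 and lay below 0 in 6 of 6 units. Its sign turned in Oligodendrocyte-like cells without Pb F2 (0.03), control F1 (0.05) or control M1 (0.01), and in cluster 10 without Pb F2, Pb M2 or control M2 (0.04 each). It turned too with doublets kept (0.03 in cluster 10) and at Leiden resolution 0.5 (0.03 there and 0.15 in Microglia-like cells). Mt1 ran from -0.44 to 0.14 in 9 units and Mt2 from -0.66 to 0.46 in 8. Fech (ferrochelatase) ran from -0.28 to 0.17 in 7 units, Slc39a8 (a zinc and manganese importer) from -0.22 to 0.36 in 5 and Slc11a2 (a divalent metal transporter) from -0.26 to 0.69 in 3. By edgeR 0 of these genes passed in any unit (smallest adjusted p = 0.488), and 0 passed by DESeq2 (smallest adjusted p = 0.360) or limma-voom (0.315). At an unadjusted p the smallest edgeR value was 0.000235, for Mt2 in Pericyte-like cells.

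Gene lists fixed in advance were then tested in each unit with limma's camera, which asks whether a list's genes rank above or below the other genes. Of 227 tests of 28 lists, 54 passed an adjusted p of 0.05 (38 higher and 16 lower in Pb mice), led by heat shock proteins, myelin genes and mitochondrial-encoded genes. With a correlation estimated from the data in place of the preset 0.01, 0 of the 54 held (smallest adjusted p = 0.223). The fry test gave 0 lists that moved one way (smallest adjusted p = 0.310) and 4 that changed in either direction: heat shock (adjusted p = 0.0404) and unfolded protein response (0.0412) in Oligodendrocyte-like cells, NF-kB and cytokines in Smooth muscle-like cells (0.00366) and unfolded protein response in cluster 0 (0.00903). Leaving out each mouse in turn, 24 of the 54 calls held in every fit. Fold changes below are means over a list's tested members on the log2 scale; in none of the called lists did the median, the mean and the test differ in sign.

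Heat shock proteins and chaperones, which refold damaged proteins, were higher in Pb mice in all 9 units with the preset correlation, and in none with an estimated correlation. The mean log2 fold change was 0.61 in Microglia-like (16 of 17 members above 0, adjusted p = 1.43e-22), 0.53 in Smooth muscle-like (13 of 15, 8.16e-18) and 0.49 in Pericyte-like cells (17 of 17, 3.63e-17), each with an adjusted p = 0.291 with an estimated correlation. It was 0.37 in all cells (17 of 18, 1.69e-12) and 0.47 in cluster 10 (16 of 16, 4.48e-18), both again with an adjusted p = 0.291 with an estimated correlation. It was 0.49 in Astrocyte-like (11 of 12, 9.84e-07; adjusted p = 0.307 with an estimated correlation) and 0.40 in Oligodendrocyte-like cells (18 of 18, 5.07e-18; adjusted p = 0.223 with an estimated correlation). The value was 0.19 in cluster 0 (15 of 18, 6.46e-05) and 0.21 in cluster 11 (8 of 12, 0.0353), both with an adjusted p = 0.582 with an estimated correlation. In Microglia-like cells Hsph1 had a log2 fold change of 1.15 (SE 0.28; 305 against 142 CPM) and Hspd1 0.75 (SE 0.18; 320 against 194 CPM), and in cluster 10 Hsp90aa1 had 0.74 (SE 0.16; 1714 against 1013 CPM). Adjusted over the list alone, 61 of 143 tests passed, each higher in Pb mice: 14 in Microglia-like, 10 in Pericyte-like, 10 in Smooth muscle-like and 9 in Oligodendrocyte-like cells, against 0 over all genes. Further ones were 7 in cluster 10, 5 in all cells, 3 in Astrocyte-like cells (Hspa1a, Hspa8, Hspb1), 2 in cluster 0 (Hspe1, Cryab) and 1 in cluster 11 (Cryab). The cold-induced genes Rbm3 and Cirbp had a median log2 fold change of -0.46 over the units. In cluster 11 the call ended without Pb F1 (adjusted p = 0.0983), Pb M2 (0.0625, mean 0.38), control F2 (0.148) or control M2 (0.138), and in cluster 0 the mean was 0.12 without control F2.

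**Figure D2:**
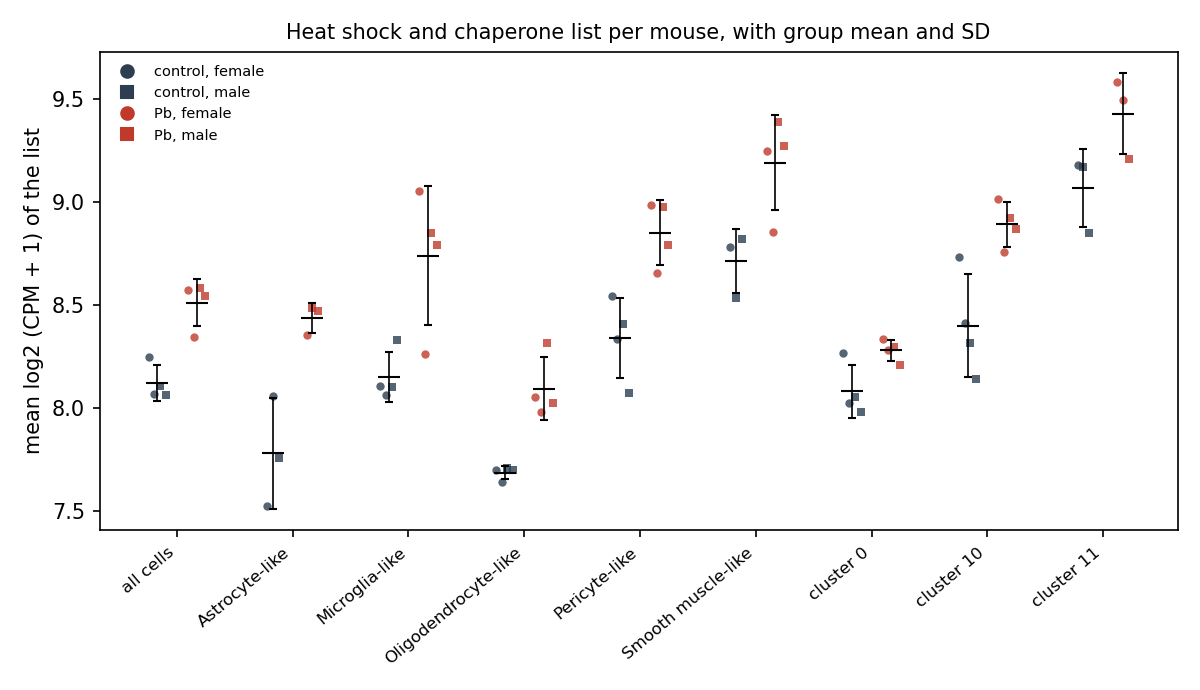
Mean log2 (CPM + 1) of the heat shock and chaperone list (vertical axis) in each tested unit, with 1 point per mouse marked by exposure and sex, and the mean and SD of each group. In all cells the Pb mice lie between 8.34 and 8.58 and the control mice between 8.06 and 8.25.

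Myelin genes were higher in Pb mice in all cells and in 6 classes or clusters other than the Oligodendrocyte-like class, where the list was not called; it was not called in cluster 10 either. The mean log2 fold change was 0.40 in all cells (22 of 24 members above 0, adjusted p = 1.24e-18; adjusted p = 0.482 with an estimated correlation), beside the higher share of Oligodendrocyte-like cells in these mice (26.1% against 19.96%). It was 0.39 in Microglia-like cells (18 of 22, 3.77e-09), 0.32 in Pericyte-like cells (13 of 16, 5.59e-06) and 0.31 in cluster 0 (17 of 21, 3.85e-07), each with an adjusted p = 0.582 with an estimated correlation. In Astrocyte-like cells it was 0.39 (10 of 12, 0.00976; adjusted p = 0.731 with an estimated correlation). In Smooth muscle-like cells it was 0.19 (9 of 14, 0.0336; adjusted p = 0.796 with an estimated correlation) and in cluster 11 0.39 (6 of 9, 0.00271; adjusted p = 0.582 with an estimated correlation). Sox10, the transcription factor of the oligodendrocyte lineage, had a log2 fold change of 1.01 in Microglia-like cells and 1.02 in cluster 0, and Mog, a myelin surface protein gene, 1.44 in Astrocyte-like cells. Mbp and Bcas1 went the other way in Smooth muscle-like cells, with log2 fold changes of -1.10 and -1.33 in the fit with no low-count filter. Over the classes other than oligodendrocytes, 14 further oligodendrocyte transcripts had a median log2 fold change of 0.23. Adjusted over the list alone, 31 of 158 tests passed as higher and 3 as lower (12 in all cells, 7 in Microglia-like cells, 4 in cluster 0; 5 higher and 3 lower in Smooth muscle-like cells), against 0 over all genes. The call ended in Astrocyte-like cells without Pb F1 (adjusted p = 0.176) or Pb M2 (0.0709, mean 0.24), and in cluster 11 without Pb M2 (0.0576) or control M2 (0.104, mean 0.25). It ended in Smooth muscle-like cells without Pb F1 (0.0860), Pb M1 (0.134), Pb M2 (0.0519) or control M2 (0.735, mean 0.06), where the mean was 0.34 without control M1. The mean was 0.25 without Pb F1 and 0.26 without control M2 in Microglia-like cells, and 0.19 without control M2 in cluster 0.

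**Figure D3:**
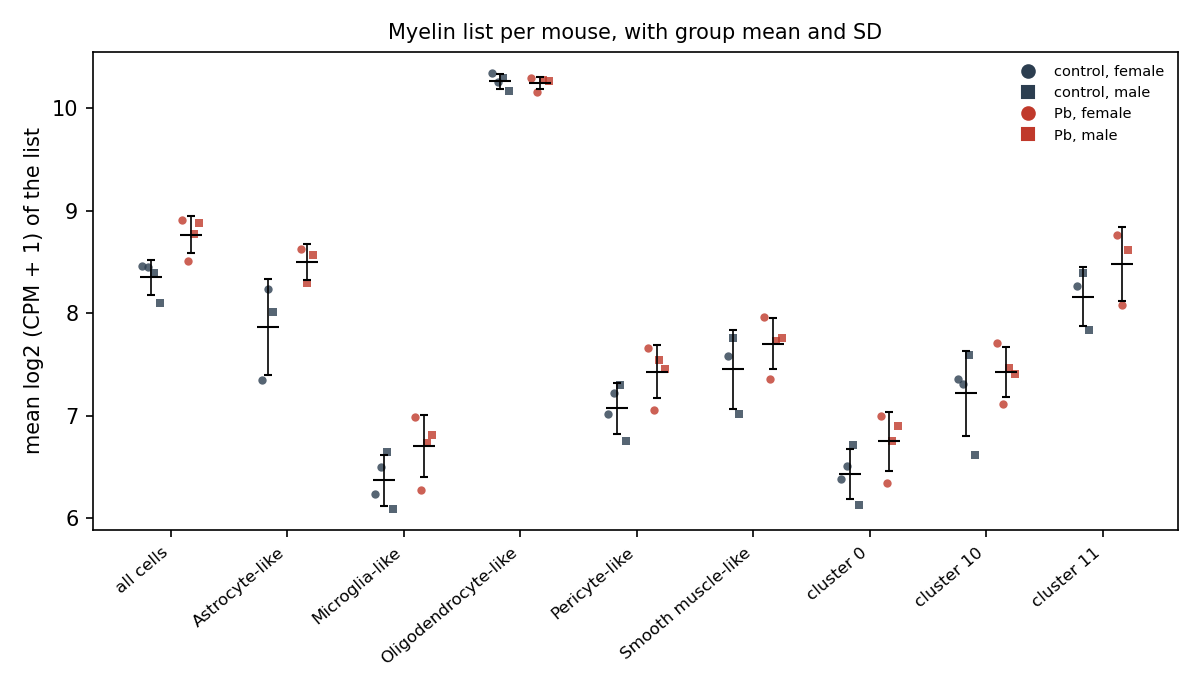
Mean log2 (CPM + 1) of the myelin list (vertical axis) in each tested unit, with 1 point per mouse marked by exposure and sex, and the mean and SD of each group. In all cells the list averages 8.77 ± 0.182 in Pb and 8.35 ± 0.172 in control mice (SD, n = 4 each).

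Genes encoded by the mitochondrial genome, which code for subunits of the respiratory chain, were lower in Pb mice in 7 units. The mean log2 fold change was -0.41 in all cells (adjusted p = 3.32e-07; adjusted p = 0.730 with an estimated correlation), -0.35 in Microglia-like (1.40e-08; adjusted p = 0.681 with an estimated correlation). It was -0.22 in Oligodendrocyte-like (5.69e-06; adjusted p = 0.731 with an estimated correlation) and -0.25 in Pericyte-like cells (1.81e-07; adjusted p = 0.668 with an estimated correlation). It was -0.33 in Smooth muscle-like cells (1.37e-08; adjusted p = 0.482 with an estimated correlation), -0.33 in cluster 0 (6.49e-12) and -0.34 in cluster 10 (8.70e-11), the last pair with an adjusted p = 0.582 with an estimated correlation. These went with the lower median mitochondrial share of UMIs in Pb mice (3.24% against 3.94%). mt-Nd5 had log2 fold changes of -0.66 in all cells, -0.61 in Microglia-like and -0.57 in Pericyte-like cells. Adjusted over the list alone, 20 of 115 tests passed as lower (10 in cluster 10, 9 in cluster 0 and mt-Nd5 in Pericyte-like cells), against 0 over all genes. No call ended when 1 mouse was left out, but without control F1 the mean was -0.20 in Microglia-like, -0.13 in Oligodendrocyte-like and -0.14 in Pericyte-like cells, -0.21 in cluster 0 and -0.23 in cluster 10. Without control M2 it was -0.22 in all cells. There it was -0.27 without Choroid plexus-like and Ependymal-like cells, a setting chosen after seeing the data. The median mitochondrial share was 10.8% in the 104 Choroid plexus-like cells, 47 of them from control M2. Without control F2 it was -0.62, -0.35 and -0.40 in those 3 classes, -0.53 in cluster 0 and -0.54 in cluster 10.

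Immediate early genes, whose transcripts appear within minutes of a stimulus and also during tissue dissociation, were lower in Pb mice in 4 units. The mean log2 fold change was -0.21 in all cells (adjusted p = 6.21e-05; adjusted p = 0.796 with an estimated correlation), -0.25 in Oligodendrocyte-like cells (1.12e-06; adjusted p = 0.621 with an estimated correlation). It was -0.24 in cluster 0 (5.07e-11; adjusted p = 0.582 with an estimated correlation) and -0.17 in cluster 10 (1.11e-05; adjusted p = 0.731 with an estimated correlation). Egr1 in cluster 0 stood at 371 against 633 CPM (log2 fold change -0.77, SE 0.19), and Ier2 in Oligodendrocyte-like cells at 177 against 249 CPM (-0.53, SE 0.14). Adjusted over the list alone, 9 of 197 tests passed as lower: Fos, Junb, Egr1, Ier2 and Btg2 in cluster 0, and Fos, Junb, Ier2 and Zfp36 in cluster 10, against 0 over all genes. In all cells the call ended without control M1 (adjusted p = 0.265, mean -0.08), and the mean was -0.37 without control M2. Without control M1 the mean was -0.14 in Oligodendrocyte-like cells and -0.16 in cluster 0, and without control F1 it was -0.09 in cluster 10.

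NF-kB targets and cytokines, genes of inflammatory signalling, were higher in Pb mice in 5 units. The mean log2 fold change was 0.28 in Microglia-like cells (21 of 25 members above 0, adjusted p = 1.19e-05; adjusted p = 0.582 with an estimated correlation) and 0.28 in all cells (0.00119; adjusted p = 0.731 with an estimated correlation). It was 0.23 in Pericyte-like (0.0218) and 0.24 in Smooth muscle-like cells (0.0338) and 0.32 in cluster 10 (0.0103), each with an adjusted p = 0.582 with an estimated correlation. Cxcl2, a neutrophil chemokine gene, had a log2 fold change of 1.06 in Microglia-like cells, Ccl4 0.82 in Smooth muscle-like cells, and Tnfaip3, which encodes an inhibitor of NF-kB, 1.06 (SE 0.32) in cluster 10. Adjusted over the list alone, 5 of 130 tests passed as higher (Ccl3 and Ccl4 in Smooth muscle-like, Cxcl10 in Microglia-like, Ccl3 in Astrocyte-like cells, Tnfaip3 in cluster 10), against 0 over all genes. In Microglia-like cells the mean was 0.19 without Pb M1 and 0.44 without control F2. In all cells the call ended without control F1 (adjusted p = 0.0816) or control M2 (0.152, mean 0.14), and the mean was 0.12 without Pb M1 and 0.46 without control F2. It ended in Pericyte-like cells without Pb F1 (0.0618), Pb M1 (0.197, mean 0.11) or control M2 (0.102). In Smooth muscle-like cells it ended without Pb F1 (0.146), Pb M1 (0.143), control F1 (0.644, mean 0.04) or control M2 (0.0772), where the mean was 0.40 without control M1. In cluster 10 it ended without Pb F1 (0.0764), Pb M1 (0.114), control F1 (0.0934) or control M1 (0.419, mean 0.05), and the mean was 0.51 without control F2.

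The unfolded protein response, which expands the folding capacity of the endoplasmic reticulum, was higher in Pb mice in Oligodendrocyte-like cells (mean log2 fold change 0.19, adjusted p = 1.10e-07; adjusted p = 0.223 with an estimated correlation). It was also higher in Pericyte-like cells (0.16, 0.00382) and cluster 0 (0.11, 0.0143), both with an adjusted p = 0.582 with an estimated correlation. Calr, the chaperone calreticulin, stood at 417 against 313 CPM in Oligodendrocyte-like cells (log2 fold change 0.40, SE 0.11), and Xbp1, a transcription factor of this response, at 136 against 91.6 CPM in cluster 0 (0.55, SE 0.14). Xbp1 was the 1 of 165 tests to pass adjusted over the list alone, against 0 over all genes. The call ended in Pericyte-like cells without control M2 (adjusted p = 0.202, mean 0.09) and in cluster 0 without Pb M1 (0.143) or control M2 (0.0889), where the mean was 0.19 without control F2.

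Antigen presentation genes were higher in Pb mice in cluster 10 (mean log2 fold change 0.18, adjusted p = 0.00444; adjusted p = 0.633 with an estimated correlation) and in Astrocyte-like cells (0.34, 0.0327; adjusted p = 0.736 with an estimated correlation). H2-Q7, a class I histocompatibility gene with near-identical relatives that can share its reads, had a log2 fold change of 1.47 (SE 0.41) in cluster 10. Adjusted over the list alone, it and Cd74 in Microglia-like cells passed, 2 of 105 tests, against 0 over all genes. In cluster 10 the call ended without Pb F2 (adjusted p = 0.0511, mean 0.11), Pb M1 (0.0812, mean 0.10) or control F1 (0.0510), and the mean was 0.27 without Pb F1 and 0.28 without Pb M2. In Astrocyte-like cells it ended without Pb M1 (0.0606), control F1 (0.0572) or control M2 (0.581, mean 0.17), and the mean was 0.72 without Pb F1 and 0.51 without control F2. Interferon response genes were higher in cluster 0 (mean 0.12, adjusted p = 0.0149; adjusted p = 0.868 with an estimated correlation) and in cluster 10 (0.14, 0.0410; adjusted p = 0.731 with an estimated correlation). There Bst2, an antiviral membrane protein gene, had a log2 fold change of 0.53. In cluster 0 that call ended without Pb F2 (0.106, mean 0.08), Pb M1 (0.945, mean -0.02), control M1 (0.124, mean 0.07) or control M2 (0.198, mean 0.07), and the mean was 0.23 without Pb F1. In cluster 10 it ended without Pb F2 (0.106), Pb M1 (0.313, mean 0.09), control F2 (0.103) or control M1 (0.266, mean 0.08). Of the interferon response genes, 0 passed adjusted over the list alone.

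Astrocyte glutamate and ion homeostasis genes were higher in Oligodendrocyte-like (mean log2 fold change 0.18, adjusted p = 0.0290; adjusted p = 0.810 with an estimated correlation) and Pericyte-like cells (0.17, 0.0428; adjusted p = 0.731 with an estimated correlation). The first call ended without Pb F2 (0.0511), Pb M1 (0.245, mean 0.10), Pb M2 (0.107), control M1 (0.242, mean 0.10) or control M2 (0.386, mean 0.08), with means of 0.29 without Pb F1 and 0.35 without control F2. Without cluster 19, chosen after seeing the data, its mean was 0.10 and it did not pass (camera adjusted p = 0.247). The second ended without Pb M1 (0.285, mean 0.07), Pb M2 (0.113), control M1 (0.157, mean 0.11) or control M2 (0.202), with means of 0.31 without control F1 and 0.27 without control F2. Reactive astrocyte genes were higher in cluster 10 (0.19, 0.00556; adjusted p = 0.482 with an estimated correlation). That call ended without Pb F2 (0.0511, mean 0.08), Pb M1 (0.422, mean 0.02), control F2 (0.0942, mean 0.08), control M1 (0.129, mean 0.07) or control M2 (0.0913, mean 0.11). Of its 80 tests, 4 passed as higher and 1 as lower adjusted over the list alone (0 in cluster 10) and 0 over all genes. Metal binding and transport genes were lower in Pericyte-like cells (-0.17, 0.0149; adjusted p = 0.505 with an estimated correlation). There Mt1, Mt2 and Tfrc, the transferrin receptor gene (log2 fold change -0.58, SE 0.18), were the 3 of 118 tests to pass adjusted over the list alone, against 0 over all genes. That call ended without Pb F2 (0.0536), Pb M1 (0.0758) or control M1 (0.217, mean -0.10).

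In all cells, blood-brain barrier genes were lower (mean log2 fold change -0.18, adjusted p = 0.00612; adjusted p = 0.868 with an estimated correlation) and cholesterol synthesis genes higher (0.12, 0.0353; adjusted p = 0.830 with an estimated correlation). These stood beside a higher share of Oligodendrocyte-like cells in Pb mice (26.1% against 19.96%) and shares of 17.6% against 18.5% for cluster 0 and 8.19% against 9.05% for cluster 10, the clusters with endothelial markers. Within these the barrier list was not called (mean -0.01, adjusted p = 0.937, in cluster 0 and -0.10, adjusted p = 0.317, in cluster 10). The first call ended without Pb F1 (0.584, mean -0.04), control F1 (0.135, mean -0.10) or control M1 (0.820, mean -0.05), with a mean of -0.37 without control M2. The second ended without Pb F1 (0.291), Pb M1 (0.0711), Pb M2 (0.0625), control M1 (0.224, mean 0.06) or control M2 (0.0562). Glycolysis genes were higher in Astrocyte-like cells (0.25, 0.0288; adjusted p = 0.582 with an estimated correlation), which ended without Pb F1 (0.0836), control F2 (0.0998, mean 0.09) or control M2 (0.198). Proteasome genes were higher in all cells (0.09, 0.00181; adjusted p = 0.868 with an estimated correlation; ended without control M2 at 0.678 with a mean of 0.02, mean 0.15 without control M1). They were higher too in Oligodendrocyte-like cells (0.08, 0.00955) and cluster 0 (0.10, 0.0123), both with an adjusted p = 0.830 with an estimated correlation. These ended in Oligodendrocyte-like cells without Pb F1 (0.477, mean 0.03), control F2 (0.0741) or control M2 (0.238, mean 0.04), with means of 0.13 without control M1 and 0.12 without Pb F2, and in cluster 0 without control M2 (0.735, mean 0.02), with a mean of 0.15 without control M1. Nuclear oxidative phosphorylation genes were lower in Smooth muscle-like cells (-0.09, 0.0319; adjusted p = 0.868 with an estimated correlation) and all cells (-0.08, 0.0385; adjusted p = 0.900 with an estimated correlation). The former ended without Pb F2 (0.155), Pb M2 (0.369, mean -0.06), control F1 (0.0561), control M1 (0.202) or control M2 (0.186). The latter ended without Pb F2 (0.972, mean -0.02), Pb M1 (0.227), Pb M2 (0.196), control F2 (0.111) or control M2 (0.817, mean 0.01), with means of -0.15 without Pb F1 and -0.12 without control M1. Without Choroid plexus-like and Ependymal-like cells, a setting chosen after seeing the data, its mean was of the other sign (0.02, with 44 of 73 members above 0) and did not pass (camera, limma; adjusted p = 0.518).

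Ribosomal protein genes were higher in Microglia-like (mean log2 fold change 0.09, adjusted p = 2.02e-06) and Oligodendrocyte-like cells (0.04, 0.00177), both with an adjusted p = 0.868 with an estimated correlation. They were lower in Astrocyte-like cells (-0.12, 0.0362; adjusted p = 0.892 with an estimated correlation). The first of these ended without control F2 (0.229, mean 0.02), with means of 0.17 without Pb F1, 0.06 without control M1, 0.05 without Pb F2 and 0.20 without control F1. The second ended without control F2 (0.106, mean 0.02), with means of 0.06 without Pb F1 and 0.08 without control F1, and the last without Pb F1 (0.0502), Pb M2 (0.597, mean -0.07), control F2 (0.777, mean -0.08) or control M2 (0.672, mean -0.05). Lists that were called in no unit were the Alzheimer-related genes (medians -0.18 to 0.03, smallest adjusted p = 0.449), DNA methylation and chromatin (-0.13 to 0.06, 0.161), NRF2 and glutathione antioxidants (-0.13 to 0.13, 0.0676), calcium signalling (-0.08 to 0.10, 0.264) and complement and phagocytosis (-0.09 to 0.15, 0.0829). The same held for disease-associated microglia (-0.10 to 0.21, 0.116), homeostatic microglia (-0.07 to 0.18, 0.202), heme synthesis (-0.01 to 0.16, 0.205), p53 and apoptosis (-0.35 to 0.12, 0.101) and synapse and NMDA receptor genes (-0.09 to 0.05, 0.403). Hemoglobin and other free RNA, tested in 3 units, had medians of -1.99 to -0.89 by voom (0.0719). By edgeR 4 of 5 members lay above 0 in cluster 0, 2 of 6 in all cells and 0 of 5 in Smooth muscle-like cells, so the direction in cluster 0 depends on the fit. Msmo1 passed adjusted over the list alone as higher in Pericyte-like cells (1 of 99 cholesterol tests), Mapt as higher in all cells (1 of 147 Alzheimer-related tests). Gas6 passed as lower in Oligodendrocyte-like cells (1 of 139 complement tests) and Hbb-bs as lower in cluster 10 (1 of 31), each against 0 over all genes. The lists for which no such count is given had 0.

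Whether the response to lead differed between the sexes was tested as the interaction of exposure and sex. In Pericyte-like cells the difference passed for Slc1a2, the main glutamate transporter gene of astrocytes, and Hbb-bs, a hemoglobin beta gene. The log2 fold change of Slc1a2 with lead was -1.46 in females and 2.40 in males (interaction 3.86, SE 0.62), and that of Hbb-bs -2.35 and 2.62 (interaction 4.97, SE 0.81), both at an edgeR adjusted p = 0.0404. Slc1a2 stood at 43.4 and 20.5 CPM in Pb F1 and Pb F2, 132 and 80.1 in Pb M1 and Pb M2, 116 and 83.7 in control F1 and control F2, and 20.4 and 17.0 in control M1 and control M2. For Hbb-bs these values were 24.8 and 123, 1803 and 495, 263 and 369, and 192 and 170.2 CPM. Hbb-bs has near-identical neighbours (Hbb-bt among them) that can share its reads, and astrocyte and hemoglobin transcripts are those of other cells than pericytes. On GRCm38 Slc1a2 lies on chromosome 2 from 102658659 to 102790784 and Hbb-bs on chromosome 7 from 103826534 to 103828096. Slc1a2 passed only without Pb M2 when 1 mouse was left out. Its interaction (adjusted p) was 4.604 (0.153) without Pb F1, 3.56 (0.191) without Pb F2 and 3.48 (0.158) without Pb M1. It was 3.64 (0.274) without control F1, 4.14 (0.196) without control F2, 4.04 (0.258) without control M1 and 3.77 (0.132) without control M2. Hbb-bs passed without Pb F2 or Pb M2, and was 3.99 (0.402) without Pb F1, 3.73 (0.0983) without Pb M1, 5.15 (0.246) without control F1, 4.70 (0.706) without control F2, 5.10 (0.184) without control M1 and 4.91 (0.132) without control M2. DESeq2 called 1 gene in these cells (Slc1a2; Hbb-bs 0.9999) and limma-voom 0 (0.919 and 0.142). Both calls also ended in edgeR when counts were thinned to the lowest total (adjusted p = 0.120 for Slc1a2 and 0.0978 for Hbb-bs), with no mitochondrial limit (0.116 and 0.0777) and at Leiden resolution 0.5 (0.0766 and 0.673).

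By edgeR 0 genes passed for the interaction in the other 5 units fitted, where 355 (all cells), 267 (Microglia-like), 202 (Oligodendrocyte-like), 239 (cluster 0) and 166 (cluster 10) had an unadjusted p under 0.05, against 240 in Pericyte-like cells. DESeq2 called 13 in all cells (Gja1, adjusted p = 0.0156, Ncan, 0.0451, and Scg3, 0.0498, among them) and 0 in the rest, and limma-voom 0. Over the 33906 tests of the classes and clusters together, 0 passed in edgeR (smallest adjusted p = 0.249). Genes with the smallest p (interaction) were Gja1 (1.77), Scg3 (1.68) and Ncan (2.34) in all cells, Hba-a1 (3.77), Slc1a2 (2.22) and Cpe (1.46) in Microglia-like cells, and Cpe (1.23) and Slc1a2 (2.18) in Oligodendrocyte-like cells. They were Hbb-bt (9.72, but -0.80 with doublets kept), Rpl36-ps3 (1.28) and Gm10800 (2.78) in cluster 0 and Slc1a2 (2.50), Gm26870 (2.24) and Gm2000 (1.497) in cluster 10. Leaving out 1 mouse gave up to 2 interaction calls: 2 without Pb F2 in Microglia-like cells, 1 without Pb F2 or control M1 in Oligodendrocyte-like cells, 2 without Pb M2 or control M1 in cluster 0, and 1 without Pb F2 and 2 without control M1 in cluster 10.

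Males and females were compared across both exposure groups, which also checks the sex given in the labels. Xist, the RNA that silences one X chromosome, stood at 912 ± 80.1 CPM in females and 1.31 CPM in males (SD, n = 4 each; log2 fold change -9.65, SE 0.49). The Y-linked genes Ddx3y (93.2 ± 3.90 CPM), Eif2s3y (41.1 ± 7.54), Uty (13.8) and Kdm5d (13.3) were found in males (n = 4) and at 0 in females. Their fitted fold therefore depends on the prior count. These 5 were the genes called in all cells by edgeR. Xist lies on chromosome X from 103460366 to 103483254 on GRCm38 and overlaps the antisense gene Tsix (103431517 to 103484957), so reads in the stretch they share cannot be told apart without strand. Beyond sex-linked genes, Pericyte-like cells of males had less Mt2 (log2 fold change -0.87, SE 0.14; 396 ± 109 against 733 ± 220.1 CPM, SD, n = 4 each; edgeR adjusted p = 0.0158) and Net1 (-1.28; 0.0267). Smooth muscle-like cells of males had more Acta2, the smooth muscle actin gene (0.95; 2656 against 1376 CPM), and less of the interferon-induced gene Ifi27l2a (-1.77) and the amino acid transporter gene Slc7a5 (-1.34). In Microglia-like cells H2-Q6, a class I histocompatibility gene with near-identical relatives, was lower in males (-1.55; 26.8 ± 12.3 against 76.6 ± 14.2 CPM, SD, n = 4 each; edgeR adjusted p = 0.0409). Astrocyte-like cells of males had more Gm26825 (2.52; 0.0197), Igfbp5 (1.73) and Fxyd6 (3.20; 0.0333), cluster 0 had less Xdh (-1.005) and Ifi27l2a (-2.23) in males, and cluster 10 more Vegfc (1.41), a vascular growth factor gene, and Alox12 (1.24).

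edgeR called 5 genes between the sexes in all cells, 5 in Microglia-like, 4 in Oligodendrocyte-like, 5 in Astrocyte-like, 5 in Pericyte-like and 5 in Smooth muscle-like cells, 11 in cluster 0, 5 in cluster 10 and 1 in cluster 11. Over all 42424 tests of the classes and clusters together 39 passed. Leaving out 1 mouse moved these counts by over 1.5 times in all cells (3 without Pb M1, Pb M2 or control M1), Astrocyte-like cells (2 without Pb F1, 9 without Pb M1, 24 without Pb M2, 3 without control F1, 1 without control F2) and Microglia-like cells (9 without Pb M1). It did so too in Oligodendrocyte-like cells (8 without Pb F1, 7 without control F1 or M1, 9 without control M2) and Pericyte-like cells (9 without control M2). The same held for Smooth muscle-like cells (1 without Pb F1, 2 without Pb F2 or control F1, 8 without control M1) and cluster 0 (6 without control F2, 7 without control M1), and for cluster 10 (3 without Pb M1, 2 without control F2, 10 without control M1) and cluster 11 (3 without Pb F2). Of 41 named calls between the sexes, 25 held in every fit without 1 mouse in which they were tested (Xist in Smooth muscle-like cells in 5 of 7 fits, Tsix in cluster 10 in 7 of 8), and the others ended as follows (edgeR adjusted p). In all cells Uty ended without Pb M1 (0.134), control M1 (0.0629) or Pb M2 (0.121), and Kdm5d without the same mice (0.147, 0.0592 and 0.165). In Astrocyte-like cells Ddx3y ended without Pb F1 (0.249), control M2 (0.0785) or control F2 (0.0717), Gm26825 without the same mice (0.249, 0.9995 and 0.421). Igfbp5 ended there without Pb F1 (0.411), control F1 (0.0557), control M2 (0.725) or control F2 (0.612), and Fxyd6 without Pb F1 (0.599), control F1 (0.0557) or control F2 (0.212, log2 fold change 4.85). Its log2 fold change was 7.80 without control M2. H2-Q6 in Microglia-like cells ended without control M1 (0.119), Pb F2 (0.169), control F1 (0.274), Pb M2 (0.301), control M2 (0.0917) or control F2 (0.142). Mt2 in Pericyte-like cells ended without Pb F1 (0.0746), Pb M1 (0.127) or control F1 (0.0693), and Net1 without Pb F1 (0.0651), Pb M1 (0.137), control M1 (0.0998), Pb F2 (0.0996), Pb M2 (0.229) or control F2 (0.0507). In Smooth muscle-like cells Ifi27l2a ended without Pb F1 (0.216), Pb F2 (0.0699) or control F1 (0.204), Slc7a5 without Pb F1 (0.216), Pb M1 (0.145) or control F1 (0.427). Acta2 ended without Pb F1 (0.248), Pb M1 (0.516), Pb F2 (0.177) or control F1 (0.470). In cluster 0 Xdh ended without Pb M1 (0.134), control M1 (0.126), Pb F2 (0.135), control F1 (0.108) or control F2 (0.112), and Ifi27l2a without Pb F1 (0.0543) or control M1 (0.112). In cluster 10 Vegfc ended without Pb F1 (0.193), Pb M1 (0.194), control F1 (0.0691), Pb M2 (0.0696), control M2 (0.0594) or control F2 (0.164), and Alox12 without those mice (0.193, 0.190, 0.0820, 0.112, 0.0639 and 0.216) or control M1 (0.0517). Of the calls in these units, some also ended with counts thinned (Igfbp5, H2-Q6, Net1, Slc7a5, Acta2, Xdh, Vegfc, Alox12), by DESeq2 (Gm26825, Igfbp5, Fxyd6, Alox12) or limma-voom (these but Alox12, and Ddx3y), with doublets kept (Igfbp5, Fxyd6, Acta2, Vegfc, Alox12), at Leiden resolution 0.5 (H2-Q6, Mt2, Net1, Ifi27l2a in cluster 0, Vegfc, Alox12) or 2.0 (Vegfc, Alox12), with another mitochondrial limit (Acta2, Xdh, Alox12) or a minimum of 20 cells (Vegfc, Alox12), and without mitochondrial and ribosomal protein genes (Acta2).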

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

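The counts of splits were chosen only after the results were seen, and the test of hemoglobin genes was moved after seeing the data to a fit with no low-count filter, because no other hemoglobin gene had passed the filter.

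In Pericyte-like cells Slc1a2 (interaction 3.86) and Hbb-bs (4.97) moved in opposite directions with lead in the sexes. RNA from blood is a candidate source for Hbb-bs: Hbb-bt, Hba-a1 and Hba-a2 had a median interaction of 7.22 in the fit with no low-count filter, and their UMIs lay mostly in Pb M1 (190, 436 and 407) and Pb M2 (53, 123 and 109). RNA from astrocytes stays open for Slc1a2: Gja1 (0.63), Slc1a3 (2.05) and Aldoc (-0.03) had a median of 0.63, between the bounds set. The Astrocyte-like share moved likewise (females -2.7 points, males 4.13). A sex difference in the response to lead, untested beyond the interaction, stays open.

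In 27 of 403 groups of 4 mice 1 mouse stood apart from the others by Dixon's test, which chance alone does in about 1 in 20 groups. Among library measures and shares these were the median UMIs per cell of control M1 (5842; other controls 6403 to 6469), the Choroid plexus-like share of Pb F1 (3.72%; others 0 to 0.277%) and the Ependymal-like share of control M2 (2.74%; others 0 to 0.272%). Among list means (log2 CPM) they were the immediate early genes of Pb F2 in all cells (9.22; others 9.07 to 9.10) and the heat shock list of control F2 in Oligodendrocyte-like cells (7.64; others 7.70 to 7.71).

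Single genes with a mouse apart (log2 CPM) were, in all cells, Ptgds in Pb M1 (12.09), Hsph1 in control F1 (7.43) and Dhcr7 in control F2 (4.33). In Microglia-like cells they were Mt1 in control F2 (10.95) and Hmox1 (7.98), Fech (4.41) and Rpl35 (10.78) in Pb F2. Oligodendrocyte-like cells had Hmox1 in Pb F2 (5.20) and Rpl6l in control M2 (8.27), and Pericyte-like cells Cryab (7.87) and Calr (8.58) in Pb F2. Smooth muscle-like cells had Fech in Pb M2 (4.85) and Ccl4 in Pb F1 (8.43). In cluster 0 these were Ptgds in control F2 (9.69), Ermn in control M1 (5.50), Mt1 in Pb M1 (10.12) and Cryab in Pb F2 (7.63). Cluster 10 had Mt2 in control M2 (7.62), Hmox1 (4.21) and Tnfaip3 (4.92) in Pb F2, Icam1 in control M1 (4.79) and Bst2 in control F1 (6.93).

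Other values moved in opposite directions with lead in females and males in every mouse. For the Astrocyte-like share (-2.70 and 4.13 points, difference 6.83), the share of cluster 15 (-0.160 and 0.484 points, difference 0.643) and the astrocyte glutamate list in Oligodendrocyte-like cells (-0.23 and 0.60, difference 0.83) that difference was not tested. For Mt2 in Microglia-like cells (-0.12 and 0.55, difference 0.67) and Cpe in Oligodendrocyte-like cells (-0.19 and 1.05, difference 1.25) the interaction did not pass in edgeR (0.71, adjusted p = 0.9999, and 1.23, adjusted p = 0.9998).

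For genes between Pb and control mice, the splits decide nothing about chance: the real count was 0, which all 34 splits that could be fitted in 7 units reach by construction. The highest other count was 76 in all cells, 62 in Oligodendrocyte-like, 32 in Microglia-like, 6 in Pericyte-like and 6 in Smooth muscle-like cells, 15 in cluster 0 and 20 in cluster 10. Splits that call many genes point to a structure of the samples, which was not tested; in all cells 3 of the other splits called any gene (12, 49 and 76). For males against females chance could not be excluded by these counts either, with 2 of 34 splits as large (3 in cluster 10): the real and highest other counts were 5 and 17 in all cells, 5 and 27 in Microglia-like, 4 and 59 in Oligodendrocyte-like, 5 and 6 in Pericyte-like and 5 and 5 in Smooth muscle-like cells, 11 and 14 in cluster 0 and 5 and 20 in cluster 10. These counts leave out the size of a difference. For Xist chance is argued against by the size of its difference (912 against 1.31 CPM in all cells) and its edgeR adjusted p in Microglia-like cells (1.20e-11 over all 42424 tests), and it held in every fit without 1 mouse in which it was tested. In Astrocyte-like cells and cluster 11 the 9 splits are too few for a share under 0.05: real and highest other counts were 0 and 5 and 0 and 2 for exposure, and 5 and 5 and 1 and 1 for sex.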

How the results depend on the processing

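The settings without cluster 19, without Choroid plexus-like and Ependymal-like cells, the splits with no low-count filter and the permutation test of list means were chosen after seeing the data. Over all settings, left-out mice included, 627 values for comparisons were rated the same, 109 moved and 29 reversed, with counts judged by size. Among single genes and lists 4937 stayed, 331 no longer passed, 70 newly passed and 68 reversed. The cause of the changes below was not tested, except that thinning and leaving out a mouse remove counts or samples. The smallest tested sums were 48525 UMIs in Astrocyte-like cells and 65558 in cluster 11, where 2285 and 1648 genes passed the low-count filter, against 12640 in all cells; genes below it were not tested. No value could be had for Smooth muscle-like cells and cluster 15 at Leiden resolution 0.5, nor for cluster 15 with doublets kept.

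DESeq2 called 29 genes for Pb in all cells and 1 in Oligodendrocyte-like cells (edgeR 0), 13 for the interaction in all cells (0) and 1 in Pericyte-like cells (2). For sex it called 15 in all cells (5), 2 in Astrocyte-like (5), 12 in Microglia-like (5) and 7 in Oligodendrocyte-like cells (4). With limma-voom sex gave 1 in Astrocyte-like cells and the interaction 0 in Pericyte-like cells.

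Thinned to the lowest total, sex gave 8 genes in all cells, 1 in Astrocyte-like, 3 in Pericyte-like, 3 in Smooth muscle-like cells, 7 in cluster 0 (11) and 2 in cluster 10 (5), and the interaction 0 in Pericyte-like cells.

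With no low-count filter, a fit whose p-values are doubtful, Pb gave 5 genes in Astrocyte-like, 60 in Microglia-like, 25 in Oligodendrocyte-like, 21 in Pericyte-like and 15 in Smooth muscle-like cells, 24 in cluster 0, 26 in cluster 10 and 1 in cluster 11. Sex gave 14, 34, 36, 23, 26, 49, 41 and 5 in the same order. The interaction gave 51 in Microglia-like, 44 in Oligodendrocyte-like and 12 in Pericyte-like cells, 25 in cluster 0 and 11 in cluster 10. For Pb, chance could not be excluded for these counts: of 34 splits of the mice with no filter, 11 gave as many in Microglia-like (highest other 137), 25 in Oligodendrocyte-like (212), 14 in Pericyte-like (50) and 16 in Smooth muscle-like cells (33), 25 in cluster 0 (111) and 12 in cluster 10 (54).

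With doublets kept, sex gave 3 genes in Astrocyte-like cells and 2 in cluster 10, where the interaction gave 3 and Pb 2. A mitochondrial limit of 10% gave 8 for sex in Astrocyte-like cells; no mitochondrial limit gave 0 for the interaction in Pericyte-like cells and 2 for Pb in cluster 10. Leiden resolution 0.5 gave 0 for the interaction in Pericyte-like cells and 2 for sex in cluster 10; resolution 2.0 also gave 2 there. A minimum of 20 cells gave 1 for Pb in cluster 10.

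The replicate numbers do not pair the mice: in all cells, correlations of the deviations of same-numbered mice were -0.39 (F1), -0.11 (F2), 0.016 (M1) and -0.18 (M2), and no Pb mouse correlated best with its own number. The replicate block in place of sex gave 8 genes for Pb in Astrocyte-like cells and 3 in cluster 11, and 48 called lists, 44 of them among the 54. Under the block, Mt2 in Oligodendrocyte-like cells was 0.015, Fech there -0.072, Mt1 in Smooth muscle-like cells 0.057, Fech in cluster 10 -0.057 and Mt1 in cluster 11 -0.12, each of the other sign.

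Of the 54 called lists, 0 passed with an estimated correlation, 0 with fry's test of 1 direction (4 with its test of change in either direction). The permutation test of list means gave 0, but decides nothing: its smallest possible p is 0.0286 (0.1 with 3 against 3 mice), which 227 tests leave at 0.649. Without Choroid plexus-like and Ependymal-like cells 54 lists were called, with nuclear oxidative phosphorylation in all cells at 0.016 (-0.077) and not called. Without cluster 19 there were 55. Newly called were the unfolded protein response in all cells (0.12) in the former, and antigen presentation (-0.48) and blood-brain barrier genes (-0.27) in Oligodendrocyte-like cells in the latter. These 3 did not hold either (adjusted p = 0.352, adjusted p = 0.716 and adjusted p = 0.716 with an estimated correlation).

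Shares of the other sign were, as centred log ratios, Fibroblast-like 0.031, Microglia-like 0.075, Pericyte-like 0.094, Smooth muscle-like 0.035, cluster 0 0.11, cluster 10 0.076 and cluster 11 0.088. The Fibroblast-like share differed by 0.036 points with a mitochondrial limit of 10% (-0.074), and that of cluster 10 by 0.36 at Leiden resolution 2.0 (-0.87).

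Single genes that reversed, none of them past the threshold, were Fech in Oligodendrocyte-like cells (0.0056; -0.015 with DESeq2, -0.00070 with limma-voom, -0.011 with no sex covariate, -0.017 without cluster 19), Mt2 there (-0.012; 0.021 with no low-count filter, 0.13 without cluster 19) and Fech in cluster 10 (0.058; -0.010 with DESeq2). With doublets kept, Alad in cluster 10 was 0.031, Slc39a8 there 0.13 and the interaction of Hbb-bt in cluster 0 -0.80 (9.72). Slc39a8 in cluster 10 was 0.065 with no mitochondrial limit and 0.19 at Leiden resolution 0.5, where Alad was 0.028 in cluster 10 and 0.15 in Microglia-like cells. Mt1 in cluster 10 was 0.027 at resolution 2.0.

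Leaving out each mouse in turn, counts for Pb ranged from 0 to 11 in Astrocyte-like, 0 to 5 in Microglia-like, 0 to 3 in Oligodendrocyte-like, 0 to 1 in Pericyte-like and 0 to 6 in Smooth muscle-like cells, 0 to 1 in cluster 0 and 0 to 2 in cluster 10. Counts for sex ranged from 3 to 6 in all cells, 1 to 24 in Astrocyte-like, 4 to 9 in Microglia-like, 4 to 9 in Oligodendrocyte-like, 4 to 9 in Pericyte-like and 1 to 8 in Smooth muscle-like cells, 6 to 15 in cluster 0, 2 to 10 in cluster 10 and 1 to 3 in cluster 11. The interaction ranged from 0 to 2 in Microglia-like, 0 to 1 in Oligodendrocyte-like and 0 to 2 in Pericyte-like cells, 0 to 2 in cluster 0 and 0 to 2 in cluster 10. Share differences ranged from -0.268 to 1.80 points for Astrocyte-like, -2.95 to 0.352 for Choroid plexus-like, -0.291 to 0.0717 for Fibroblast-like, -1.67 to 0.330 for Pericyte-like and -0.332 to 0.296 for Perivascular macrophage-like cells, and from -2.60 to 0.506 for cluster 0, -2.06 to 0.280 for cluster 10 and -0.447 to 0.371 for cluster 11. Nuclear oxidative phosphorylation in all cells ranged from -0.15 to 0.0090 and the interferon response in cluster 0 from -0.016 to 0.23.

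Log2 fold changes of metal and heme genes that changed sign ranged, for Mt1, from -0.10 to 0.092 in all cells, -0.31 to 0.0013 in Astrocyte-like, -0.011 to 0.18 in Microglia-like and -0.17 to 0.10 in Smooth muscle-like cells, -0.27 to 0.029 in cluster 0 and -0.49 to 0.65 in cluster 11. Mt2 ranged from -0.094 to 0.091 in Oligodendrocyte-like cells and -0.48 to 0.016 in cluster 10, and Hmox1 from -0.23 to 0.30 in cluster 0 and -0.019 to 0.51 in cluster 10. Fech ranged from -0.0060 to 0.29 in all cells, -0.12 to 0.20 in Oligodendrocyte-like, -0.26 to 0.44 in Pericyte-like and -0.13 to 0.048 in Smooth muscle-like cells, -0.21 to 0.62 in cluster 0 and -0.31 to 0.23 in cluster 10. Alad ranged from -0.39 to 0.051 in Oligodendrocyte-like cells and -0.18 to 0.041 in cluster 10, Slc11a2 from -0.056 to 0.38 in all cells and -0.43 to 0.049 in Oligodendrocyte-like cells, and Slc39a8 from -0.64 to 0.12 in Pericyte-like cells and -0.14 to 0.086 in cluster 10.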

Other observations

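The test of immediate early genes, the counts of splits and the permutation test of list means were chosen only after the results were seen.

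Heat shock genes had higher values in Pb mice in each tested unit. A dissociation response that raises immediate early and heat shock genes together stays open: the median of the immediate early list lay below 0 in 9 of 9 units, but the list was called in 4, in none with an estimated correlation, and its mean per mouse was lower in Pb mice by over 2 SE in 1 of 9 (cluster 0) and 0.11 higher in Astrocyte-like cells. Warmer handling of the Pb tissue may account for the pattern: cold-induced Rbm3 and Cirbp had a median log2 fold change of -0.46 (16 of 17 values below 0). Rbm3 in Oligodendrocyte-like cells, seen first, was left out, but units are not independent: all cells hold the others. Free RNA shared by all droplets stays open: the difference in summed CPM was 2.61 times as large in Microglia-like cells (7593) as in cluster 0 (2908), a gap of 4685 (SE 2794). A response to lead itself stays open too, as the labels give no handling batches.

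Myelin genes had higher values in Pb mice in classes other than oligodendrocytes. RNA from oligodendrocytes is a candidate explanation: 14 other oligodendrocyte transcripts had a median log2 fold change of 0.23 over those classes (84 values; 0.34 in Microglia-like cells, 0.07 in cluster 10) against -0.03 in Oligodendrocyte-like cells. A larger share of oligodendrocytes feeding the free RNA may contribute, since the share of Oligodendrocyte-like cells and the myelin mean in Microglia-like cells correlated across the 8 mice (Pearson's r = 0.843, permutation p = 0.00568; Spearman's rho = 0.881, permutation p = 0.00724; 1 relation computed). Within the 4 Pb mice r was 0.863 and within the 4 control mice 0.854, too few for a test, and without the 2 mice farthest from the median share r was 0.676 (permutation p = 0.15, 6 mice), so the call, though not its direction, rests on those mice. A change within these classes was not tested separately.

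For gene lists, chance could not be excluded by counts of splits: 25 of 34 splits gave as many called lists in all cells (real 9, highest other 14), 17 in Microglia-like (5 and 11), 21 in Oligodendrocyte-like (7 and 15), 14 in Pericyte-like (7 and 11) and 19 in Smooth muscle-like cells (5 and 8), 19 in cluster 0 (7 and 14) and 8 in cluster 10 (8 and 11). In Astrocyte-like cells (5 and 7) and cluster 11 (1 and 4) the 9 splits are too few for a share under 0.05. For the mean fold of the heat shock list alone, the real split gave 0.37 in all cells and the highest other 0.34, and in Oligodendrocyte-like cells 0.40 and 0.39, where the real split was the 1 of 34 with a mean that large, for a list singled out after its result was seen. In the other 5 units with 34 splits another split gave a larger mean than the real one: 0.75 against 0.61 in Microglia-like, 0.54 against 0.49 in Pericyte-like and 0.67 against 0.53 in Smooth muscle-like cells, 0.49 against 0.47 in cluster 10 and 0.27 against 0.19 in cluster 0, where 4 of 34 splits were as large. The exact permutation test of list means passed for 0 lists after adjustment: the heat shock mean in all cells was 8.51 ± 0.113 in Pb and 8.12 ± 0.0867 in control mice (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible, adjusted 0.649), a value that the number of tests and mice sets, so it decides nothing.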
